A study of Mus musculus with 2 samples.

How the data were processed

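Hindlimb muscle RNA was sequenced on a HiSeq instrument, per the labels, from 1 floxed control and 1 floxed MyoD-Cre mouse sample, and the groups were taken from the genotype labels of the samples. The submitters' processing notes name Bowtie 0.12.2 and the mm9 build, without a role. The coordinates and chromosome lengths in the deposited tables are those of GRCm38 instead: of 19368 mRNA genes found by symbol in GENCODE M21, 19327 (99.79%) overlap it at the deposited positions. Coordinates are therefore given as in the files, on GRCm38. The counting tool, gene annotation and strand setting are not given in the sources used here.

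The authors deposited FPKM values per gene for both libraries, which are normalized to gene length and to reads per library. The deposited tables of mapping give counts of reads per chromosome and per class and, per the file headers, each chromosome's reads as a fraction of the mapped reads. Shares of reads have 95% Wilson intervals. The table holds 44787 genes with values, 22669 of them mRNA, and 1 line was empty. The symbols of 27 rows had been turned into dates, and these rows were left unnamed and counted as separate genes. No other rows shared a symbol.

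The FPKM values were used as deposited. The difference of a gene was log2((knockout FPKM + 1)/(control FPKM + 1)), with a pseudocount of 1 FPKM, which understates the differences of low genes. A gene was measured at 1 FPKM or more in at least 1 library and was called higher or lower at a difference of at least 1, a 2-fold rule of size with no test. The named genes are Srsf2, the 12 genes with the highest and 12 with the lowest difference at 5 FPKM or more in 1 library, and up to 3 members at either end of each list. For the highest and lowest genes, symbols of predicted genes (Gm with digits, or ending in Rik), symbols starting with Mir, Snor, Rnu, Scarna or n-R5, and pseudogene symbols with -ps were left out; tRNA symbols and symbols starting with LOC were not. Names outside this rule are said to be chosen later where they appear.

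The 43 gene lists hold 774 members, of which 773 were found in the table, some under older symbols. The median of each list was placed among the medians of 10000 random lists drawn within 20 bins of mean expression. A list stood apart at or below percentile 1 or at or above percentile 99 with at least 5 measured members, and 2 lists had fewer. These percentiles describe the 2 libraries and not the genotypes.

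Precision was taken from the values. Low genes gave FPKM ratios fixed at 0.95007 times ratios of small whole numbers, seen in 534 genes with 1 read in each library, so that 1 FPKM is relative to 26659452 reads in the control library and 28060573 in the knockout library. The smallest whole reads that give both values, within a relative tolerance of 2e-14, were found for 23278 of 26405 genes above 0 (88.16%) and for 11748 of 13175 measured genes (89.17%). The intervals are exact Clopper-Pearson intervals of the ratio, computed from those reads, and are at least as wide as with the true reads where the true reads are a multiple of them. The remaining genes, such as myosins, globins, mitochondrial genes and many ribosomal protein genes, have no interval. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only.

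The steps were tested on simulated data, with Poisson reads for 12875 genes at 1 FPKM or more and 200 genes changed by known folds in this comparison. The rule counted 98% of 4-fold, 92% of 3-fold, 4% of 2-fold and 0% of 1.5-fold changes in the right direction. A 1.5-fold change lies under the 2-fold rule and a 2-fold change at its edge, and the pseudocount shrinks all differences further. Of 12675 unchanged genes, the rule counted 0. The simulated reads held counting error alone, with no spread between animals or samples. This 0 is therefore not a rate of false calls in the real libraries. Intervals held the true ratio for 95.45% of genes. Of 200 random lists of 15 genes, 5 stood apart, and 100 of 100 lists raised by 0.5 did.

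Alternatives were the pseudocount, the filter, the fold of the rule, 4 scalings, and the matching of random lists, all chosen before the data were examined. Of the scalings, that to a sum of 1000000 FPKM multiplied both libraries by 2.12 and left their balance as it was. 4 further alternatives were chosen after: rescaling to the mean of both sums, mRNA genes alone, genes whose interval excludes 1, and genes at 1 FPKM or more in the control library. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.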

Results

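RNA sequencing of mouse hindlimb muscle was compared between 1 library from an animal with both Srsf2 alleles floxed (the control library) and 1 library from a floxed animal that also carried MyoD-Cre (the knockout library). Srsf2 encodes a serine- and arginine-rich (SR) protein that binds exons and takes part in splice site choice, and MyoD-Cre expresses the Cre recombinase in the myogenic lineage. The comparison addressed how the muscle transcriptome differed when Srsf2 was deleted in that lineage. The control library held 69422626 reads and the knockout library 76702198, of which 81.426% (95% Wilson interval 81.417 to 81.436) and 79.993% (79.985 to 80.002) were mapped. Reads across exon junctions made up 38.2% of the mapped reads in the control library and 35.7% in the knockout library. Each genotype was represented by 1 library, so no difference below has a replicate check, no p-value is given, and "higher" and "lower" describe these 2 libraries. Intervals of ratios cover counting error only.

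Srsf2 itself (chromosome 11, 116849904 to 116853106, minus strand) had a lower value in the knockout library, short of the rule of size used below, at 19.4 FPKM (a fragment count normalised to gene length and library size) against 31.1 FPKM in the control library. The ratio of knockout to control was 0.624, with a 95% counting interval of 0.584 to 0.666, from 1469 and 2238 recovered reads. This direction goes with the labels of the libraries. The part of the gene that is floxed is not given in the sources used here, so reads outside the deleted part and reads from cells without Cre can both enter the gene-level value.

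Skin keratinocyte genes showed the largest differences of the comparison. 4 genes of the fast fibre list were among the 12 genes with the lowest differences taken by the naming rule. Krt1 and Krt10, the keratin pair of differentiated epidermal cells, were at 669 and 906 FPKM in the knockout library against 2.48 and 3.89 FPKM in the control library, ratios of 269 (231 to 316) and 233 (204 to 267). Pvalb, the calcium-binding protein parvalbumin of fast fibres, was at 8.02 FPKM against 56.7 FPKM, a ratio of 0.141 (0.125 to 0.160). Myod1, a transcription factor of myogenic determination, was at 3.58 FPKM against 10.6 FPKM, a ratio of 0.337 (0.263 to 0.429). Only the knockout animal carried MyoD-Cre, so an effect of the Cre allele itself, on Myod1 or on other genes, cannot be told apart from loss of Srsf2. Ucp3, an uncoupling protein of muscle mitochondria, was at 1.60 FPKM against 8.37 FPKM.

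Among 13175 genes at 1 FPKM or more in at least 1 library, 353 were higher and 98 were lower in the knockout library by the rule of size, a difference of at least 1 on the log2(FPKM + 1) scale. Of the 353 higher genes, 222 lay under 1 FPKM in the control library. Among mRNA genes 281 were higher and 42 lower (87.0% higher), and among genes whose counting interval excluded a ratio of 1 there were 272 and 60, both chosen after the data were seen. Higher genes made up 78.3% of those past the rule, and this split depended on the scaling of the libraries: it was 62.1% after median-of-ratios scaling, 62.5% after TMM scaling and 59.9% when the 50 most abundant genes were left out of the scaling. The median gene lay at 0.18 on the log2 scale with the values as deposited and at 0.02, 0.02 and -0.002 under those scalings, so gene groups are also described relative to the median gene. Those 50 genes took 54.2% of the summed FPKM in the control library and 46.8% in the knockout library. Across genes, which are not independent replicates, the libraries had a Pearson correlation of 0.962 and a Spearman correlation of 0.951 on that scale.

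The other genes with the highest differences were Flg, Calm4, Dmkn, Lor, Krt5, Stfa3, Lgals7, Asprv1, Krt14 and Dsp. Flg and Lor encode filaggrin and loricrin of the cornified layer, Krt5 and Krt14 form the keratin pair of basal epidermal cells, and Dsp encodes desmoplakin of desmosomes. Lor was at 60.1 FPKM against 0.274 FPKM, Krt5 at 65.3 FPKM against 0.394 FPKM and Dsp at 35.1 FPKM against 0.231 FPKM. The reads of Flg were not recovered as whole numbers, so its values of 118 and 0.262 FPKM have no counting interval. The remaining genes with the lowest differences were Lrtm1, Myh4, Mybpc2, LOC101056072, Myh1, Rpl3l, Hspb6, n-Tp12 and Atcayos. Myh4 and Myh1 encode the fast myosin heavy chains IIb and IIx and were at 16.9 and 29.2 FPKM in the knockout library against 69.3 and 93.9 FPKM, and Mybpc2, fast myosin-binding protein C, was at 20.7 FPKM against 70.7 FPKM. The tRNA gene n-Tp12 lies inside the span of Myh8 on the same strand, and Atcayos overlaps Atcay on the other strand, so reads of these transcripts cannot be told apart from those of their hosts without strand and splice information.

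**Figure D1:**
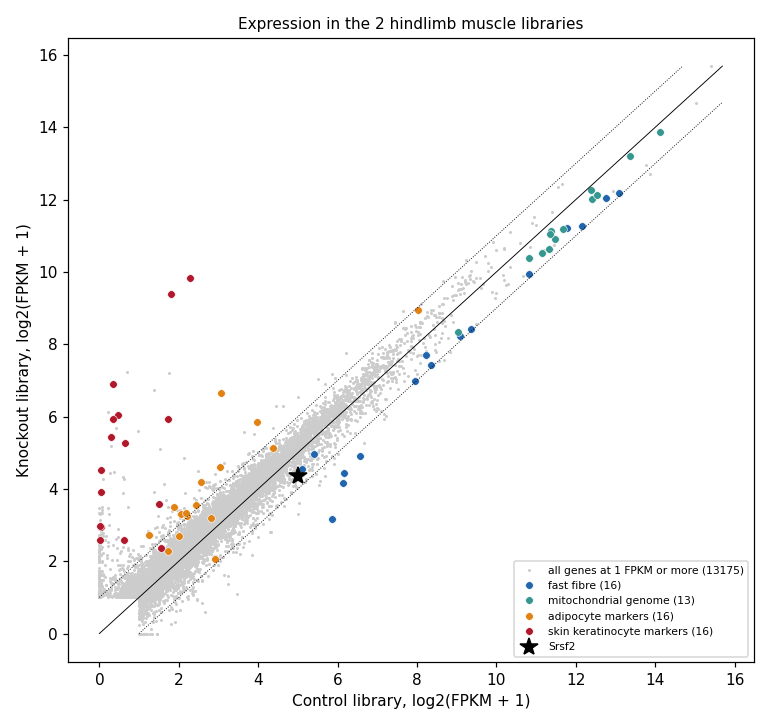
Log2(FPKM + 1) of each gene in the control library (x axis) and the knockout library (y axis), 1 point per gene at 1 FPKM or more in at least 1 library, with the members of 4 gene lists coloured, Srsf2 as a star, a solid line of equality and dotted lines at a difference of 1. Keratinocyte markers lie far above the line (list median 4.33), 15 of 16 adipocyte markers above it (1.15), and fast fibre and mitochondrial genome genes below it (-0.90 and -0.40).

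Of 43 gene lists fixed before the data were examined, 41 had at least 5 measured members. Of these, 24 stood apart from 10000 random lists of the same size and mean expression, 12 with high medians and 12 with low ones. By chance, 0.82 lists were expected if the genes within each list varied independently of each other, like genes drawn at random. Whether they did was not tested, and genes that vary together within a list would make 0.82 too low. Lists of muscle fibres and sarcomeres lay low. All 16 measured fast fibre genes were below the median gene and 4 were lower by the rule (list median -0.90, percentile 0), from Pvalb to Myh2 at 30.4 FPKM against 41.6 FPKM. Sarcomere structure genes had a median of -0.46 (percentile 0), with 24 of 26 below the median gene. Among them Myot, a Z-disc protein, was at 143 FPKM against 257 FPKM, and Myom3, an M-band protein, went the other way at 37.5 FPKM against 28.0 FPKM. The slow fibre list had a median of -0.21 (percentile 0.16) and was mixed. Its Myl3, a slow myosin light chain, was lower at 30.4 FPKM against 63.1 FPKM, while Tnni1, slow troponin I, was at 158 FPKM against 119 FPKM with a ratio of 1.33 (1.27 to 1.38).

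Embryonic and perinatal muscle genes did not stand apart (median -0.06, percentile 2.63) and held members past the rule in both directions. Myh8, the perinatal myosin heavy chain, was lower at 6684 FPKM against 15047 FPKM. Myl4, the embryonic myosin light chain, was higher at 556 FPKM against 275 FPKM, a ratio of 2.02 (1.98 to 2.06), and Chrng, the fetal subunit of the acetylcholine receptor, was at 20.95 FPKM against 11.6 FPKM. Reads of Myh1, Myh4, Myh7 and Myh8 were not recovered as whole numbers, which leaves open how reads shared between these similar genes were divided. Satellite cell and myogenic factors had a median of -0.16 (percentile 0.05), with 12 of 15 below the median gene and 1, Myod1, lower by the rule. In that list Myog, a factor of myogenic differentiation, was at 42.0 FPKM against 53.8 FPKM and Cdh15, M-cadherin, at 21.6 FPKM against 13.7 FPKM. Myoblast fusion genes did not stand apart (median 0.30, percentile 82.62, 7 measured).

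Lists of the membrane and of excitation lay low as well. Excitation-contraction coupling genes had a median of -0.40 (percentile 0), and Jph1, a junctophilin that joins the tubules to the sarcoplasmic reticulum, was lower by the rule at 20.3 FPKM against 42.8 FPKM. Ryr1, the calcium release channel, was at 40.0 FPKM against 62.9 FPKM. Dystrophin complex and membrane repair genes had a median of -0.20 (percentile 0) with none past the rule, and Sntb1, a syntrophin, was at 17.3 FPKM against 29.2 FPKM. Neuromuscular junction genes had a median of -0.10 (percentile 0.15) but were mixed, with 6 of 13 above 0, 7 below 0 and none past the rule. Ache was at 5.17 FPKM against 9.11 FPKM, and this list no longer stood apart among genes at 5 FPKM or more (percentile 1.09).

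The 4 lists of energy metabolism stood apart low, with few members past the rule. All 18 glycolysis and glycogen genes lay below the median gene (list median -0.38, percentile 0), and 2 of them, Eno3, the muscle enolase, and Phkg1, a phosphorylase kinase subunit, passed the rule at 183 FPKM against 373 FPKM and 3.02 FPKM against 7.28 FPKM. All 13 protein-coding genes of the mitochondrial genome had values below those of the control library (median -0.40, percentile 0.04, none past the rule), from ND4 at 1588 FPKM against 2568 FPKM to ATP8. Nuclear-encoded oxidative phosphorylation genes had a median of -0.14 (percentile 0), with 29 of 30 below the median gene and none past the rule. Fatty acid oxidation genes had a median of -0.25 (percentile 0), with 1 of 18 genes, Ucp3, lower by the rule, while Lpl, lipoprotein lipase, was at 78.6 FPKM against 56.3 FPKM.

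Markers of several other tissues were high in the same library. Of 17 keratinocyte markers, 16 reached 1 FPKM in the knockout library and 5 in the control library, and 15 were higher by the rule (median 4.33, percentile 100). Adipocyte markers had a median of 1.15 (percentile 100), with 10 of 16 higher, among them Scd1, stearoyl-CoA desaturase, at 99.97 FPKM against 7.30 FPKM and Adipoq, adiponectin, at 56.2 FPKM against 14.6 FPKM, whereas Plin4 was at 3.17 FPKM against 6.57 FPKM. Extracellular matrix genes had a median of 0.51 (percentile 100), with 23 of 26 above the median gene and none past the rule, and Col1a1 was at 2208 FPKM against 1301 FPKM. Cartilage markers had a median of 0.67 and bone markers of 0.65 (percentile 100 for both), with Col2a1 of cartilage at 32.1 FPKM against 16.4 FPKM and Dmp1 of osteocytes at 77.3 FPKM against 23.7 FPKM. Endothelial markers stood apart in the other direction (median -0.04, percentile 0.26), with Cldn5 at 11.1 FPKM against 16.6 FPKM.

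Among the other cell type lists none stood apart. Their medians and percentiles were 0.36 and 97.19 for fibroblasts and fibro-adipogenic progenitors, 0.22 and 58.28 for tendon, 0.29 and 90.1 for macrophages, 0.16 and 49.38 for neutrophils and marrow myeloid cells, 0.12 and 17.49 for smooth muscle and pericytes, and -0.07 and 1.14 for Schwann cells and nerve. The signs of the neutrophil and the smooth muscle medians changed under other scalings. Lgals3, galectin-3, was the 1 macrophage marker higher by the rule, at 10.2 FPKM against 3.39 FPKM. Erythroid markers had a median of 0.35 (percentile 94.5) and 4 higher members, all globins, such as Hbb-bs at 482 FPKM against 199 FPKM. In the same list Klf1, an erythroid transcription factor, was at 0.697 FPKM against 1.42 FPKM, and Slc4a1, the red cell anion exchanger, at 1.10 FPKM against 1.90 FPKM. The lymphocyte list had 1 measured gene, Thy1, at 5.03 FPKM against 3.11 FPKM. Xist was at 27.74 and 25.01 FPKM in the knockout and control libraries, and it was the 1 measured gene of the 5 sex-linked genes in both.

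Ribosomal protein, cell cycle, endoplasmic reticulum chaperone, integrated stress response and immediate early lists stood apart high, in the library that also held the skin and fat markers, while the cytosolic heat shock list lay low without standing apart. All 36 ribosomal protein genes were above the median gene (median 0.47, percentile 100, none past the rule), for example Rplp1 with a ratio of 1.59 (1.56 to 1.63). Mitosis genes had a median of 0.39 (percentile 99.78) with 20 of 22 above the median gene, and Cdk1, the kinase of mitotic entry, was at 9.93 FPKM against 5.69 FPKM. DNA replication genes had a median of 0.42 (percentile 99.86), and Cdt1, a licensing factor, was at 6.62 FPKM against 3.39 FPKM. No gene of either list passed the rule, and the replication list did not stand apart among genes at 5 FPKM or more (percentile 97.62). Endoplasmic reticulum chaperones had a median of 0.53 (percentile 100), with Creld2 at 7.66 FPKM against 3.83 FPKM. Integrated stress response genes had a median of 0.48 (percentile 99.93), and Nupr1, a stress-induced nuclear protein, was higher by the rule at 119 FPKM against 50.4 FPKM. Immediate early genes had a median of 0.60 (percentile 100) and 5 of 20 were higher, including Ctgf at 76.9 FPKM against 20.9 FPKM and Nr4a3 at 6.46 FPKM against 0.381 FPKM.

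The p53 target list also stood apart high (median 0.42, percentile 99.9), but its members moved in different directions, and it did not stand apart among genes at 5 FPKM or more (percentile 96.21). Perp, which is also a desmosomal protein of the epidermis, was at 47.1 FPKM against 0.947 FPKM, and Trp53inp1 was at 16.03 FPKM against 6.29 FPKM. Cdkn1a, the cell cycle inhibitor p21, was at 51.7 FPKM against 61.7 FPKM, and Ccng1 was at 43.7 FPKM against 60.1 FPKM. Apoptosis (median 0.22, percentile 68.09), atrophy and autophagy (0.28, 85.13), interferon response (0.17, 57.75), cytokine (0.35, 90.27) and Notch pathway (0.13, 33.01) lists did not stand apart, and the signs of the cytokine and Notch medians changed under other scalings. Cytosolic heat shock genes did not stand apart (median -0.06, percentile 1.37), with 2 of 14 lower by the rule, among them Hspa1a at 1.25 FPKM against 4.10 FPKM.

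Splicing factors as groups did not stand apart. The SR protein list, which contains Srsf2, had a median of 0.31 (percentile 86.26), with no member past the rule. Tra2a and Tra2b, SR-like splicing activators, were at 50.4 FPKM against 28.2 FPKM, a ratio of 1.79 (1.69 to 1.90), and at 82.5 FPKM against 48.6 FPKM, a ratio of 1.70 (1.66 to 1.74). Other splicing regulators had a median of 0.24 (percentile 65.82). In that list Esrp1, an epithelial splicing regulator, was higher by the rule at 2.33 FPKM against 0.00947 FPKM, and the muscle-enriched Rbm20 was at 7.78 FPKM against 11.5 FPKM. Exon usage was not analysed here, since the values are per gene.

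**Figure D2:**
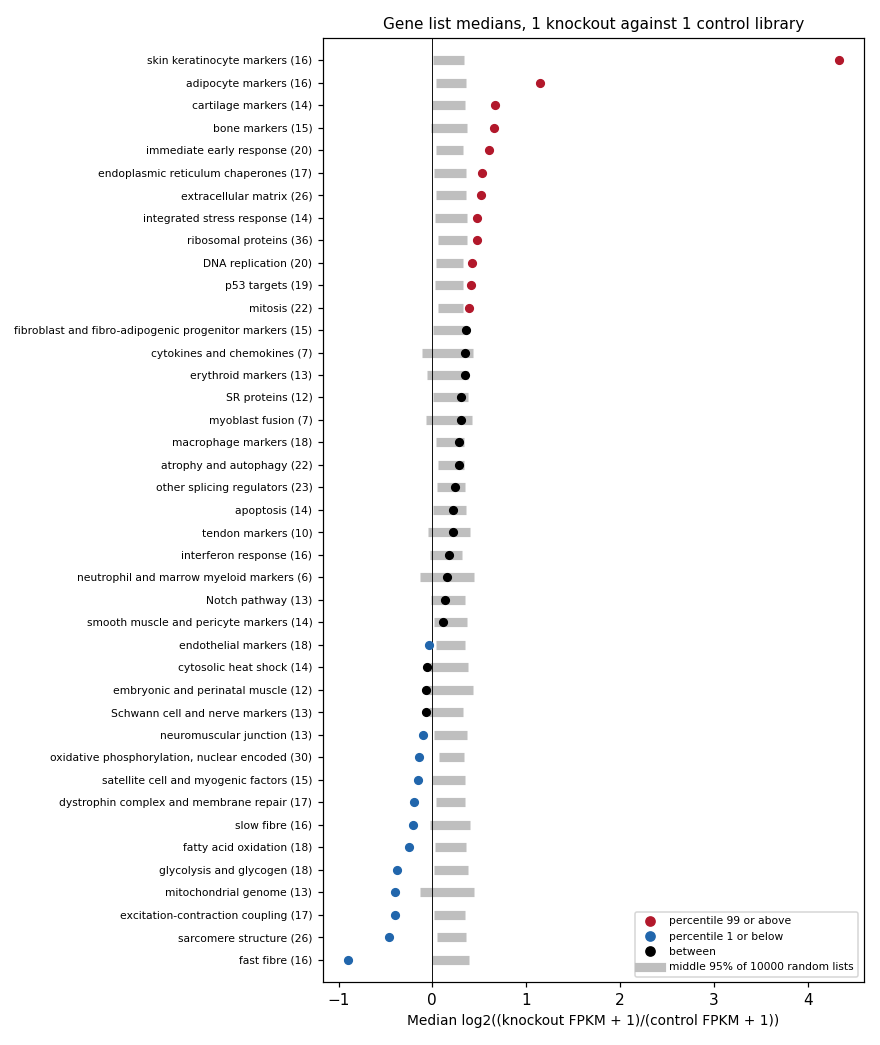
Median log2((knockout FPKM + 1)/(control FPKM + 1)) of each gene list with at least 5 measured members (dots, the number measured in brackets), against the middle 95% of 10000 random lists of matched mean expression (grey bars). The keratinocyte list lies at 4.33 and the adipocyte list at 1.15, and the fast fibre list is the lowest at -0.90.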

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

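With 1 library per group there was no library to leave out. No paired analysis was possible because each group holds 1 library. No pair of named rows shared a symbol, so keeping the row of the highest mean per symbol was not run. The cause of each change below was not tested, except that the filters and folds change which genes can count, and that rescaling to a sum of 1000000 FPKM acts through the pseudocount and filter. The deposited sums were already close (471324 and 471778 FPKM), so it multiplied both libraries by 2.12. Rescaling to the mean of both sums instead, chosen after the data were seen, gave 353 higher and 98 lower genes. 21 of the 24 lists that stood apart did so under all 11 alternatives for lists. The scalings among these shift a list and its random lists together, so they could change the percentiles of these lists little. Of 78 named genes 2, Xist and Myh3, changed sign, both from small differences.

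The counts of higher and lower genes (353 and 98) were 613 and 204 with a pseudocount of 0.1, 169 and 54 at 5 FPKM or more, 1205 and 383 with a 1.5-fold rule, 96 and 3 with a 4-fold rule (97% higher), and 605 and 212 when each library was rescaled to 1000000 FPKM. The lower genes numbered 173 under median of ratios (62.1% higher), 171 under TMM (62.5%) and 184 without the 50 most abundant genes (59.9%). In alternatives chosen after the data were seen, 42 mRNA genes were lower (87% of those past the rule were higher), 60 lower genes had an interval that excluded 1, and 131 genes were higher among those at 1 FPKM or more in the control (57.2% higher). This last filter can remove higher genes only, because any gene lower by the rule is at 1 FPKM or more in the control. Its share is therefore no check on the excess of higher genes.

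Srsf2 stood at -0.842 under median of ratios, -0.837 under TMM and -0.865 without the 50 most abundant genes, against -0.654. The correlation of the libraries was 0.9307 and 0.9539 with pseudocounts of 0.1 and 0.5, 0.9858 without a filter and 0.944 at 5 FPKM or more.

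At 5 FPKM or more the neuromuscular junction (percentile 1.09), p53 target (96.21) and DNA replication (97.62) lists no longer stood apart, and the erythroid list did (100). The erythroid list moved the other way without a filter (6.99) and rescaled to 1000000 FPKM (31.8), so its place depended on which members were measured. The Schwann cell list stood apart with pseudocounts of 0.1 and 0.5 (0.8 and 0.95), rescaled to 1000000 FPKM (0.7) and without matching (0.89), but not rescaled to the mean of both sums (1.18). The embryonic list did so without a filter (0.96) and with 5 bins (0.88), and the heat shock list without a filter (0.73), under median of ratios (0.92), with 5 bins (0.5) and without matching (0.7). Mapped reads outside the uniquely mapped class were 2.99% and 3.00% of mapped reads in the control and knockout libraries. With all reads as the denominator they were 2.43% and 2.40%. Counting depth limits genes near 1 FPKM.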

Other observations

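The genes in this paragraph were chosen after their values were seen. The microRNA genes Mir133b and Mir1a-1 were lower by the rule in the knockout library, although host transcripts can share their reads. Mir133b was at 187 FPKM against 413 FPKM, with a counting interval of the ratio from 0.411 to 0.499, and Mir1a-1 at 17.6 FPKM against 46.3 FPKM. Of all 70 histone genes, 42 reached 1 FPKM in the knockout library and 35 in the control library, and 15 were higher by the rule and none lower, among them Hist1h1b at 4.56 FPKM against 1.51 FPKM. Fasn, fatty acid synthase, at 9.13 FPKM against 3.51 FPKM, and Me1, malic enzyme, at 17.2 FPKM against 5.42 FPKM, were higher by the rule, in the library that also had high adipocyte markers. Fasn is itself a member of the adipocyte list and is already counted among its higher members, so it is not a separate observation. Of all 52 keratin genes in the table, 19 reached 1 FPKM in the knockout library and 4 in the control library, and of all 21 late cornified envelope genes 11 and 0 did.

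In what follows, 3 patterns are weighed. The tests were chosen after the results were seen, except the one on the measured genes of a second skin list. With 1 library of each genotype, a direct effect of Srsf2 loss stays open and untested for each pattern.

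Keratinocyte genes were far higher in the knockout library. Their list median of 4.33 stayed at 4.19 or above under the 3 scalings that moved the balance of the libraries. Those scalings multiplied the knockout library relative to the control by 0.859 to 0.876. They argue only against scaling of that size as the cause, and could hardly have moved the median further. An earlier version of this test, the largest move of the median, gave 0.68. That move came from rescaling each library to a sum of 1000000 FPKM, which multiplied both libraries by 2.12 and so tested no such scaling. A second skin list, written before its genes were looked up and without 1 gene already seen among the highest, gave 100% of 24 measured epidermal genes as higher, but that test was void: a gene near 0 in the control counts as measured only when it reaches 1 FPKM in the knockout, which nearly makes it higher. Over all 33 epidermal genes of that list, 24 (72.7%) reached 1 FPKM in the knockout library and 0 in the control library, against 1 in each among 10 genes of internal epithelia. Hair follicle genes reached it in 6 of 10 cases against 1, with Tchh at 16.5 FPKM against 2.07 FPKM, and of 7 melanocyte genes 1 did against 0, Dct at 5.34 FPKM against 0.381 FPKM; by any amount, all 7 melanocyte genes and 7 of the 10 internal epithelial genes were higher in the knockout library. Skin tissue in the knockout sample is therefore a candidate source of these transcripts; the labels name hindlimb muscle, and 5 of the 17 genes of the first keratinocyte list were at 1 FPKM or more in the control library.

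The fast fibre list lay low in the knockout library, with a highest list median of -1.09 over the same 3 scalings. All 3 lowered the knockout library relative to the control, so they could only lower this median, and the test cannot argue against scaling as the cause. Relative to the median gene, which such a scaling shifts as well, the list median lay at -1.08 with the values as deposited. A lower share of muscle RNA stays open: 8 slow fibre and embryonic genes, of 19 with recovered reads, had counting intervals above 1 under TMM scaling and 11 had intervals below 1, but with 1 library per group these intervals leave out the spread between animals, so the test is void. The medians of the lists of other tissues ran from -0.07 for Schwann cells and nerve to 4.33 for keratinocytes. An earlier developmental stage of the knockout animal cannot be told apart from the genotype, since the labels give no age: the ratio of Myh3 to Myh8 was 0.267 against 0.102, a log2 change of 1.39, which an earlier stage would give, but Myh3 and Myh8 reads were not recovered and can be shared between similar myosins. Other early transcripts went both ways. The fetal growth transcripts H19, Igf2, Meg3 and Dlk1 were chosen after their values were seen, and all but Meg3 belong to the embryonic list. Their ratios of knockout to control were 0.571, 0.748, 0.759 and 0.934 with the values as deposited, without counting intervals. Myl4 and Chrng, also of the embryonic list, had ratios of 1.77 and 1.58 under TMM scaling, which divides the deposited ratios by 1.141. With 1 library per group, these values do not decide the question.

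Globin genes were 2.11 to 2.42 times as high in the knockout library. If more blood were the cause, other erythroid markers would be expected to follow, and 6 of 7 with recovered reads had intervals wholly below the lowest globin ratio, 2 of them wholly below 1, but with 1 library per group these intervals leave out the spread between animals and the globin ratios have none, so the test is void. A first, looser bound on the same intervals, which would have argued against more blood, was replaced after the result was seen and is void likewise. The values went both ways. Tspan33 was at 3.26 FPKM against 1.47 FPKM and Alas2 at 9.62 FPKM against 5.12 FPKM, both chosen after their values were seen. Klf1 was lower at 0.697 FPKM against 1.42 FPKM, as was the microRNA gene Mir451, also chosen after its values were seen, at 3.46 FPKM against 13.3 FPKM. Whether more blood accounts for the pattern stays open.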
